A study of Homo sapiens with 18 samples.

How the data were processed

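Buffy coat RNA from 18 people was measured, 9 healthy and 9 with HCV cirrhosis. Per the labels' protocols, total RNA was extracted with Trizol and treated with DNase I. Reverse transcription used 1 ug of RNA, and SYBR Green PCR ran for 40 cycles on commercial 96-well arrays. Series notes state equal RNA amounts for each sample. The threshold and baseline settings and the number of replicate wells were not given in the sources used here. Samples were grouped by the disease state in their labels.

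The authors deposited 3 tables. The first holds raw Ct values per well and sample, with blanks where no Ct was given. Of its 1728 wells, 217 were blank and 50 had a Ct over 35, and values ran from 14.9 to 39.6. The second holds delta Ct values, which are on a log2 scale, as group means with SDs by the authors, per the file headers. Setting this table against the Ct values showed that the authors took RPLP0 alone as the reference and set blanks and Ct values over 35 to 35. With these settings the healthy means matched within 4.94e-07 cycles except for APOE, and the HCV means matched within 0.00111 cycles. The third table gives the authors' fold change of HCV over healthy samples, a ratio made from the group means. Its comment letters are not explained in the file.

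From the Ct table, delta Ct was recomputed with the recovered settings. Minus delta Ct was taken as log2 relative expression, which assumes that product doubles in each cycle. A gene was tested when its Ct was 35 or lower in at least 5 of the 9 samples of either group. This left 70 of 84 genes, and the 14 left out included EGFR, GPX5, GPX6, INS, MBL2, MT3, NME5, NOS1, NOS1AP, NOX5, PRG3, SCARA3 and SOD3. Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 70 genes and a threshold of 0.05. Intervals are 95% confidence intervals of the moderated fit. Detection was compared with Fisher's exact test over 84 genes. Reference genes were compared with two-sided exact permutation tests over all 48620 assignments of the samples, with Benjamini-Hochberg adjustment within each family. The tests of reference genes relative to RPLP0 and to the median gene were added after the data were seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used for these steps.

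Gene lists were written from textbook knowledge and cover nitric oxide synthesis, cGMP signalling, superoxide and oxidant generation, antioxidant defence, cytokines, the interferon response, cell death and cell cycle, vascular factors, hypoxia, chaperones and reference genes. Marker lists cover neutrophils, eosinophils, monocytes, lymphocytes, platelets, red cells, and liver and endothelium. Lists with at least 3 tested members were tested with limma's camera (preset correlation 0.01, and again with an estimated correlation) and fry, adjusted over the lists. Relative to RPLP0, camera made no call with either correlation. The list of reference genes had 5 measured and 0 tested members, because these genes were kept out of the count of calls.

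The named genes were set by rule. Up to 15 called genes in each direction with the largest log2 difference were named, and, because fewer than 20 passed, the genes with the smallest unadjusted p were added until 20 were named. NOS1, NOS2, NOS3 and the reference genes were always named. The tests, lists, naming rule and most alternatives were set before the data were examined. Those alternatives were other reference genes, their mean, the median gene or no reference, other Ct ceilings and filters, the authors' means and SDs, exact permutation and rank-sum tests, array weights, robust variance estimates, the replicate number as a block, and leaving out each sample. The mean of 4 reference genes without RPLP0, a missing SRXN1 well and the gene lists under the means of 5 and of 4 reference genes were added later.

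Results for some single genes are not reported here, although these genes stayed in every fit and count. Gene symbols are those of the file. Of 89 genes, 88 matched a RefSeq record of GRCh38.p14 by accession, and 3 have newer symbols, TESMIN for MTL5, SELENOS for VIMP and SELENOP for SEPP1. No genome coordinates were used, since the primer positions were not given in the sources used here.

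The fitting steps were tested on simulated data for HCV cirrhosis against healthy, with 70 genes and 15 changed in each of 100 simulations. The test recovered 28% of genes changed 1.5-fold, 67.6% of those changed 2-fold and 92.6% of those changed 4-fold, and 4.27% of its calls were false. The simulated genes varied independently with normal noise and changed in random directions. These shares therefore do not cover an error in the reference gene, which all real genes share. Control wells were checked as well. Means of the reverse transcription and positive PCR controls did not differ between groups (exact permutation adjusted p = 0.372 for both). Samples were checked for duplicates. The smallest SD of Ct differences between a pair of samples of a group, over 64 genes, was 0.54 cycles, against a median SD of 0.166 cycles among the positive control wells of a sample, so every sample was counted once.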

Results

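Transcript levels were measured by real-time PCR in blood buffy coat, the white cell and platelet layer of centrifuged blood, from 18 people. Of these, 9 were healthy and 9 had hepatitis C virus (HCV) infection with cirrhosis of Child class B, a middle grade of impaired liver function. Each sample was run on a 96-well array with 84 genes, 5 reference genes and 7 control wells. The array gives a threshold cycle (Ct), which is lower when more template is present. Between 68 and 72 genes per healthy sample and between 67 and 76 per HCV sample had a Ct of 35 or lower, and 64 genes reached that level in all 18 samples. The Ct of the ribosomal protein gene RPLP0, against which the authors expressed all levels, lay between 17.5 and 18.6 in healthy samples and between 17.5 and 18.9 in HCV samples. The precision of each value is limited by the 9 samples per group.

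The comparison asked which of these transcripts differed in blood leukocytes between healthy people and people with HCV cirrhosis. Relative to RPLP0, 5 of the 70 genes tested rose in HCV cirrhosis and 0 fell, and 4 of them are described here. CCNA1, which encodes a cyclin best known from meiosis and myeloid leukaemia, rose by a log2 difference of 1.82 (SE 0.49, 3.53-fold, limma adjusted p = 0.034). IL10, an anti-inflammatory cytokine, rose by 1.34 (SE 0.39, 2.52-fold, adjusted p = 0.0395). SOD2, the mitochondrial superoxide dismutase, rose by 0.87 (SE 0.24, 1.83-fold, adjusted p = 0.0356), and ATOX1, a copper chaperone, rose by 0.86 (SE 0.22, 1.82-fold, adjusted p = 0.034). CCNA1, IL10 and ATOX1 lay above the healthy median in 9 of 9 HCV samples, and SOD2 in 8 of 9. CCNA1 and IL10 were scarce, with healthy delta Ct values of 13.68 ± 1.36 and 14.01 ± 1.11 cycles above RPLP0 (SD, n = 9), whereas SOD2 lay 3.18 ± 0.41 cycles above it.

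**Figure D1:**
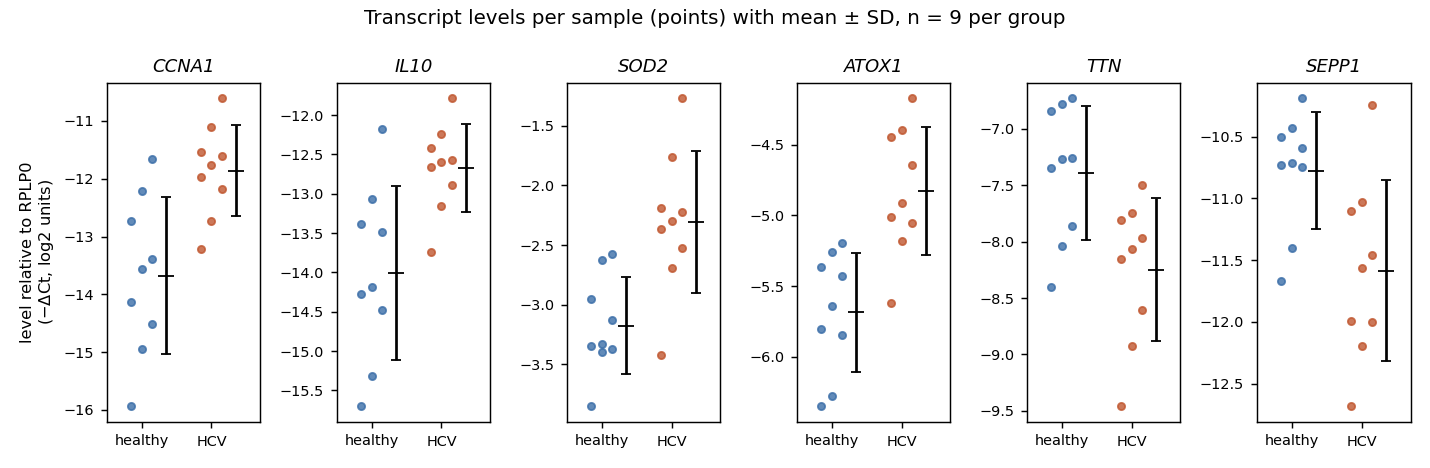
Levels of 6 transcripts relative to RPLP0 (vertical axes, minus delta Ct in log2 units, a separate scale per gene) in healthy and HCV samples. Points are samples, and the black marks give the mean with its SD for 9 samples per group. CCNA1, IL10, SOD2 and ATOX1 passed the test at log2 differences from 0.86 to 1.82, while TTN (-0.86) and SEPP1 (-0.81) did not.

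A further 15 genes had the next smallest p-values, and none of them passed the threshold in limma's test relative to RPLP0. PRDX5 and GLRX2 (adjusted p = 0.0446 each) and MPO (adjusted p = 0.0466) were among those that passed the exact permutation test. Relative to the median gene, those passing limma's test included DUSP1, MPO, NCF1 and PREX1 as higher, and TTN and SEPP1 as lower. The log2 difference relative to RPLP0 was positive for 13 of the 15, as it was for 52 of all 70 tested genes. It was 1.33 for DUSP1, a phosphatase that switches off MAP kinases (adjusted p = 0.0551), 1.33 for MPO, the myeloperoxidase of neutrophil granules (adjusted p = 0.0575), and 2.41 for CXCL8, a neutrophil chemoattractant (SE 0.89, adjusted p = 0.075). NCF1, a subunit of the phagocyte NADPH oxidase, had a difference of 0.94 (adjusted p = 0.0918). NCF1 has near-identical pseudogene copies, so its value is uncertain. Values were 0.88 for the cell cycle inhibitor CDKN1A and 0.68 for GCH1, which makes a cofactor of nitric oxide synthases. Relative to ACTB, NCF1 was at 0.26, CDKN1A at 0.20 and GCH1 at 0.003. Other positive values relative to RPLP0 were 0.59 for PREX1, 0.57 for VIMP (now SELENOS), 0.54 for PRDX5, 0.52 for NQO1, 0.51 for DYNLL1 and 0.38 for GLRX2. All of these were negative relative to ACTB. Relative to RPLP0, the titin gene TTN had a difference of -0.86 (adjusted p = 0.0618) and lay below the healthy median in 9 of 9 HCV samples. SEPP1 (now SELENOP), which encodes a secreted selenium carrier, had a difference of -0.81 (adjusted p = 0.075) and lay below it in 8 of 9.

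None of the nitric oxide synthases passed limma's test. NOS3, the endothelial form, had a log2 difference of -0.78 (SE 0.43, adjusted p = 0.163) that reached -1.46 relative to ACTB and -0.49 without 1 of the samples, and NOS2, the inducible form, had 0.07 (SE 0.58, adjusted p = 0.913). NOS2 had a Ct of 35 or lower in 8 healthy and 6 HCV samples. NOS1, the neuronal form, reached that level in 0 of 18 samples and was not tested.

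The direction of the calls depended on the reference gene. With the mean of all 5 reference genes, 0 genes rose and 3 fell. With the median of the genes detected in every sample 10 rose, among them the 5 called relative to RPLP0, and 3 fell. The log2 differences with the mean of 5 reference genes were 1.43 for CCNA1, 0.95 for IL10, 0.49 for SOD2 and 0.48 for ATOX1 (limma adjusted p from 0.104 to 0.16), and relative to ACTB they were 1.14, 0.66, 0.19 and 0.18 in the same order (limma adjusted p from 0.154 to 0.624). Leaving out 1 healthy sample, or either of 2 HCV samples, left 0 calls relative to RPLP0, with smallest adjusted p-values from 0.053 to 0.0631 in limma's test, while over all 18 such fits the differences ran from 1.53 to 2.07 for CCNA1, 1.12 to 1.56 for IL10, 0.74 to 1.01 for SOD2 and 0.78 to 0.96 for ATOX1.

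**Figure D2:**
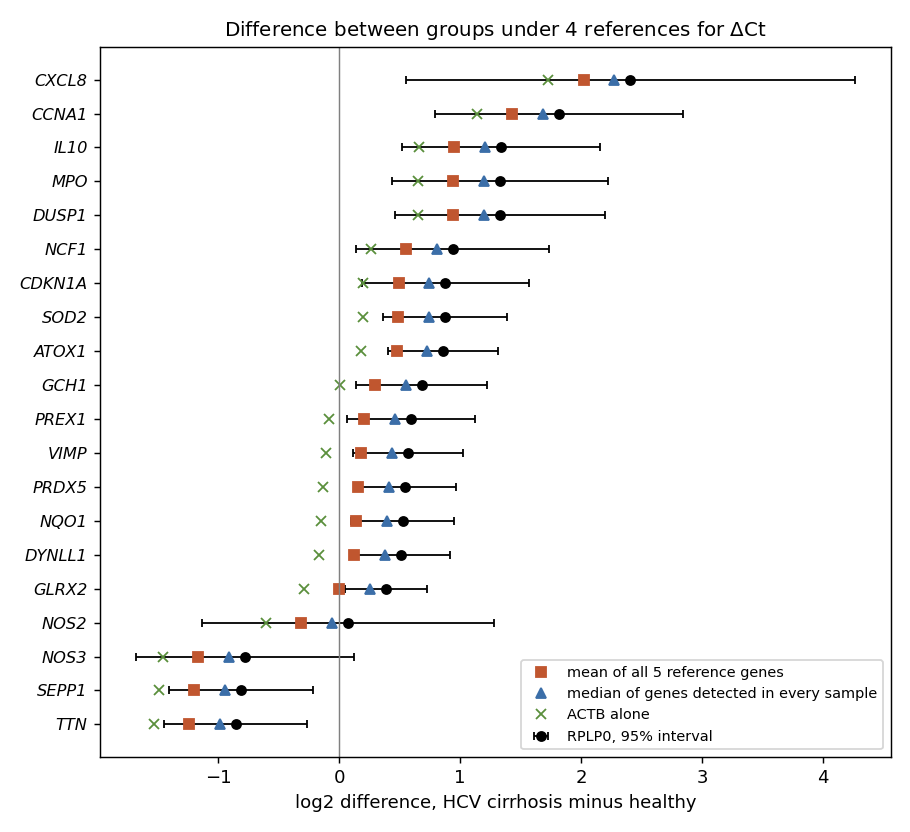
Log2 difference between HCV cirrhosis and healthy samples (horizontal axis) for 20 named genes under 4 references for delta Ct. Black points with bars give the value relative to RPLP0 and its 95% interval for 9 samples per group, and the other symbols give the values relative to the mean of 5 reference genes, the median gene and ACTB. CXCL8, CCNA1, IL10, MPO, DUSP1, SOD2, ATOX1, CDKN1A, NCF1 and GCH1 lay above 0 under all 4. DYNLL1, for example, moved from 0.51 relative to RPLP0 to -0.17 relative to ACTB.

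The gene groups fixed in advance were then compared, each by its members and by limma's camera test against the other genes. Relative to RPLP0, no group passed camera's test. Of all 70 tested genes, 52 had a positive and 18 a negative difference relative to RPLP0. The counts of positive members in each group are to be read beside that share. The list of neutrophil markers includes MPO, which is also expressed in early myeloid cells, and NCF1, of the phagocyte oxidase. Its results are therefore not specific to neutrophils. All 3 tested members had positive differences. Over all genes 1 of them rose, while all 3 passed when adjusted over the list alone. The camera adjusted p of this group was 0.218, and the adjusted p = 0.919 with an estimated correlation. Limma's fry test, which asks whether the members moved 1 way on balance, gave an adjusted p of 0.0236 relative to RPLP0 and 0.000721 relative to the median gene. Under the other references the fry call was lost, with adjusted p-values from 0.0507 (raw Ct) to 0.269 (GAPDH). Of the 8 tested genes of superoxide and oxidant generation, which share all 3 of those members, 5 were positive and 3 negative with a median of 0.33, which was -0.35 relative to ACTB. Over all genes 1 rose, and 2, among them MPO, passed when adjusted over the list alone (camera adjusted p = 0.815, fry adjusted p = 0.291). Fry's adjusted p was 0.0443 relative to the median gene and from 0.223 (ACTB) to 0.976 (HPRT1) under the other references.

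Of the 23 tested antioxidant genes, 20 had positive and 3 had negative differences, with a median of 0.29 that turned to -0.10 with the mean of 5 reference genes and to -0.39 with ACTB. SOD2 was the 1 gene called over all genes and also the 1 gene called when adjusted over the list alone. The camera adjusted p was 0.815, and fry's test for change in either direction gave an adjusted p of 0.0444, which was computed relative to RPLP0 only. The cytosolic SOD1 had a log2 difference of 0.02. The median of the other tested genes was 0.48.

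Of the 13 tested genes of nitric oxide synthesis, 9 were positive and 4 negative, with a median of 0.31 (-0.36 relative to ACTB) and 0 calls over all genes or when adjusted over the list alone (camera adjusted p = 0.815). Among 5 genes of cell death and the cell cycle, CCNA1 rose over all genes, and CCNA1 and CDKN1A passed when adjusted over the list alone (camera adjusted p = 0.815, fry adjusted p = 0.0579). Fry made a call for this group relative to the median gene (adjusted p = 0.021) and under none of the other references (adjusted p from 0.0999 with raw Ct to 0.996 with GAPDH). Of the cytokine group only CXCL8 and IL10 were tested, with IL10 called over all genes and both called when adjusted over the list alone. The vascular group held VEGFA, at 0.73, and APOE, at 0.70, with 0 calls by either adjustment. Groups or cell markers with 1 tested gene had 0 calls by either adjustment, at -0.72 for CYGB (hypoxia), 0.03 for HSP90AB1 (chaperones), -0.48 for EPX (eosinophils), 0.06 for ALOX12 (platelets), 0.07 for PRDX2 (red cells) and 0.70 for APOE (liver and endothelium). The groups for cGMP signalling, the interferon response, monocytes and lymphocytes had 0 measured genes.

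The reference genes were compared because equal RNA input was stated. The mean Ct of ACTB was 18.1 ± 0.73 in healthy and 17.5 ± 0.82 in HCV samples (SD, n = 9, exact permutation p = 0.0926), and that of RPLP0 was 18.04 ± 0.32 and 18.06 ± 0.45 (exact permutation p = 0.899). None of the 5 genes or their mean differed in raw Ct after adjustment, the smallest adjusted p being 0.344 in the exact permutation test, and 0 had an unadjusted p under 0.05. Relative to RPLP0, ACTB was 1.60-fold higher in HCV samples (exact permutation adjusted p = 0.0387) and B2M 1.27-fold higher (exact permutation adjusted p = 0.0344), each lying beyond the healthy median in 7 of 9 HCV samples. GAPDH differed by -0.59 cycles and HPRT1 by -0.32 cycles from their healthy values relative to RPLP0, both with an exact permutation adjusted p of 0.108. Relative to the median gene, ACTB differed by -0.55 cycles (exact permutation adjusted p = 0.0165) and RPLP0 by 0.13 cycles (exact permutation adjusted p = 0.506).

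Whether a gene reached a Ct of 35 or lower did not differ between groups for any of the 84 genes by Fisher's exact test, two-sided, with 0 at an unadjusted p under 0.05. The test could show no difference for the 64 genes that reached it in all 18 samples. The same holds for genes that reached it in none, such as NOS1. The smallest exact p was 0.206, for the keratin gene KRT1, which reached that level in 6 of 9 healthy and 9 of 9 HCV samples. KRT1 was chosen for mention after its values were seen.

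The fold changes in the authors' deposited table were set beside those recomputed from the Ct values. For 88 of 89 genes they matched within 1%. The exception was APOE, at 0.225 in the authors' deposited table and 1.62 when recomputed. SRXN1, a sulfiredoxin that repairs oxidised peroxiredoxins, had a fold of 4.67 in the authors' deposited table, and its 9 HCV samples included 1 well at a Ct of 14.9 while the others lay between 25.1 and 28.1. With that well left missing, an alternative added after the data were seen, the fold was 1.93. APOE and SRXN1 were singled out after their values were seen, and neither passed limma's test (adjusted p = 0.129 and 0.159). With all wells kept, SRXN1 did pass the exact permutation test (adjusted p = 0.0446), and APOE did not (adjusted p = 0.152).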

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

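The tests of RPLP0 against the other reference genes, of the SRXN1 well and of the APOE mean were chosen after the results were seen.

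The 5 called genes, among them CCNA1, IL10, SOD2 and ATOX1, were higher in HCV cirrhosis relative to RPLP0, by 1.18 on average. Random regrouping seldom gave such a count, since 1 of 100 splits of the samples, the real one, gave as many calls. The highest other split gave 2. A share below 1 in 100 could not be seen with 100 splits, so chance is made less likely and not excluded. RPLP0 itself was at -0.48 relative to the mean of the other 4 reference genes, and relative to that mean the called genes averaged 0.699 with 0 genes called higher (exact permutation p = 0.0105, which ignores that these genes were picked relative to RPLP0). Genes picked again in 100 shuffles that moved only RPLP0 averaged as high relative to that mean in 7, the real grouping included. Relative to the median gene the 5 genes stayed called by limma, with CCNA1 at 1.69, IL10 at 1.20, SOD2 at 0.74 and ATOX1 at 0.73. RPLP0 itself differed by 0.13 cycles relative to the median gene, so these differences could move little and are no separate check of RPLP0. In raw Ct, RPLP0 differed by 0.02 cycles between groups (exact permutation p = 0.899). The other 4 reference genes were lower by 0.30 to 0.65 cycles in HCV samples, none past the threshold. Raw Ct gave log2 differences of 1.79 for CCNA1, 1.31 for IL10, 0.85 for SOD2 and 0.84 for ATOX1 (limma adjusted p from 0.0713 to 0.0834). An RPLP0 that was low against the other reference genes thus cannot be told apart from a rise of these genes. A larger share of neutrophils could also raise them, but within groups and relative to the median gene the mean of CCNA1, IL10, SOD2 and ATOX1 did not follow NCF1 (r = 0.017, permutation p = 0.947), and this too stays open beside an effect of the disease because 18 samples leave r imprecise.

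SRXN1 in HCV cirrhosis had 1 sample far from the others, with a gap of 0.809 of the group's range. One aberrant well is a candidate explanation. Without it the log2 difference moved from 2.22 (SE 1.20) to 0.949 (SE 0.31), and the adjusted p in limma's test moved from 0.159 to 0.0534. In the same sample 0 of 69 other tested genes lay over 3 cycles from the median of the other HCV samples, the farthest being 2.40 cycles away, which argues against a fault of the whole sample. Its Ct of 14.9 was the lowest of all 1728 wells, below the mean HCV Ct of B2M (16.5) and RPLP0 (18.06). A true excess in that sample would thus have to place SRXN1 above every other transcript measured. It is not excluded, since no repeat of the well was analysed here.

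The fold of APOE in the authors' deposited table, 0.225, opposed the recomputed 1.62. One healthy well is blank in the Ct table, and a single Ct of 9.36 there would restore the authors' healthy mean. With that Ct the SD is 8.278, against 8.278 in the authors' deposited table, while the other healthy APOE values lay between Ct 33.6 and 36.3. One Ct thus restores both the mean and the SD, with the SDs differing by 1.40e-06. This argues that such a Ct entered the authors' mean and gave the deposited fold. Why the well is blank in the Ct table is not known, and no biological explanation of the recomputed fold was tested.

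Other samples stood apart within their group, each measured as the gap to the nearest sample divided by the group's range in delta Ct. With SRXN1 included, 16 of 148 groups of samples passed, where chance gives about 1 in 20, or 7.4, and 15 of the 16 are given here. Healthy samples with a high delta Ct gave 0.527 for CCS, 0.564 for GPX4, 0.551 for OXR1, 0.639 for SGK2 and 0.627 for B2M. Healthy samples with a low delta Ct gave 0.664 for CYGB and 0.577 for PRKAR1B. HCV samples with a low delta Ct gave 0.668 for AKT1, 0.54 for CAT, 0.494 for GLRX2, 0.561 for MPO, 0.734 for MSRA, 0.528 for PRDX6 and 0.557 for TROAP.

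The genomic DNA control well, which no comparison used, gave a Ct in 1 healthy sample, at 39.2, and in 2 HCV samples, the lowest at 36.7. These lie past the Ct ceiling of 35.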

How the results depend on the processing

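The mean of 4 reference genes, the missing SRXN1 well, the gene lists under means of reference genes and the reference genes relative to the median gene were chosen after the results were seen.

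Of 478 values of 22 named genes under the alternatives, 383 kept direction and side of the threshold, 32 gained a call and 24 changed sign. The other 39 lost the call, and all of these were among the 87 values of CCNA1, IL10, SOD2 and ATOX1. Against 5 genes higher and 0 lower by limma, other references called 3 (5-gene mean), 7 (ACTB), 3 (B2M), 2 (GAPDH) and 6 (4-gene mean), all lower, 0 with HPRT1 and 0 with raw Ct (15 and 16 at an unadjusted p under 0.05), and 13 with the median gene, 10 higher and 3 lower. The median log2 difference of all genes, 0.38 relative to RPLP0, was -0.01, -0.30, 0.03, -0.21, -0.11, 0.06, 0.35 and 0.25 in the same order. With the ceiling and the detection filter both moved to Ct 30, 58 genes were tested and 3 were called, all higher, with CCNA1 at 0.38 (limma adjusted p = 0.137). The mean Ct of CCNA1 was 31.7 in healthy and 29.9 in HCV samples, so that ceiling cuts its difference by design. Array weights gave 9 calls (7 higher and 2 lower). The exact permutation test gave 10 and the exact rank-sum test 2, all higher. CCNA1, IL10 and SOD2 lost their calls by the exact rank-sum test (adjusted p = 0.0559, 0.0675 and 0.0657). The cause was not tested. Leaving out 1 sample gave 0 to 10 calls, with 2 of them lower without 1 healthy sample and without 1 HCV sample. The count was 0 without 1 healthy or either of 2 HCV samples, and ATOX1 was called in 15 of the 18 fits, CCNA1 in 14, SOD2 in 10 and IL10 in 8. The replicate block, fitted only to samples with 1 of the 8 numbers found in both groups, left 0 calls by limma (18 at an unadjusted p under 0.05). Its differences were 2.11 for CCNA1, 1.30 for IL10, 0.89 for SOD2 and 0.88 for ATOX1. Same-numbered samples come from different people, and the labels do not say whether they were matched. Their correlations ran from -0.22 to 0.49, with 4 of 8 over 0.1, which cannot settle whether the numbers pair the samples.

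The sign of several small differences turned with the reference. Relative to ACTB and GAPDH the values were -0.14 and -0.045 for PRDX5, -0.17 and -0.075 for DYNLL1, -0.11 and -0.020 for VIMP, -0.15 and -0.064 for NQO1, and -0.29 and -0.20 for GLRX2. Relative to ACTB alone PREX1 was at -0.084. GLRX2 was at -0.0026 with the 5-gene mean and -0.10 with the 4-gene mean. NOS2 was at -0.31 (5-gene mean), -0.60 (ACTB), -0.27 (B2M), -0.51 (GAPDH), -0.25 (HPRT1), -0.059 (median gene), -0.41 (4-gene mean), -0.84 (ceiling of 40) and -0.086 (array weights), and from -0.18 to 0.34 with 1 sample left out. APOE was at -2.15 from the authors' means. The 1 gene list called by camera under the 5-gene mean, the 4-gene mean, ACTB, GAPDH or the median gene, and under 0 of the other settings, was that of neutrophil markers. With an estimated correlation its adjusted p ran from 0.222 (GAPDH) to 0.402 (5-gene mean). Relative to the median gene 1 reference gene differed, where 2 did relative to RPLP0. Fold changes matched the authors' deposited table for 17 of 89 genes with arithmetic means and for 0 with other references, since the authors used means of delta Ct and RPLP0. Blanks and high Ct values, which mark scarce transcripts such as NOS2, limit what can be measured.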

Other observations

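The genes in the next paragraph were chosen after their values under other references were seen, as were KRT1, TROAP and GRIN2D.

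Several transcripts were lower in HCV cirrhosis under other references. Relative to RPLP0 none fell in the limma test over all 18 samples, although 2 genes were called lower with array weights, among them SEPP1 (-0.98, adjusted p = 0.0268). SEPP1 was called lower under 6 of 8 other references and TTN under 5, DUOX1 and PRKCA under 4 each, SGK2 under 2, and EPX under 1, in limma's test. Each of these references moves every gene down by the same amount relative to RPLP0, so their signs could not have turned. Relative to RPLP0 the log2 differences were -0.87 for DUOX1, an epithelial oxidase, -0.82 for the kinase gene SGK2, -0.33 for the protein kinase C gene PRKCA and -0.48 for EPX, the peroxidase of eosinophils. DUOX1, EPX and NOS3 lay below the healthy median in 8 of 9 HCV samples.

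Scarce transcripts with a wide spread also had positive differences that did not pass limma's test. KRT1 was at 2.34 (SE 1.09, adjusted p = 0.123), TROAP at 1.00 (SE 0.44, adjusted p = 0.12) and GRIN2D at 1.02 (SE 0.48, adjusted p = 0.127). TROAP lay above the healthy median in 7 of 9 HCV samples and GRIN2D in 6 of 9.

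DUSP1 and CXCL8 are induced quickly by stress or activation, as is JUN, so a shared response may underlie their positive differences. Across 18 samples, relative to the median gene and with group means removed, DUSP1 rose with the mean of JUN and CXCL8 (r = 0.799, permutation p = 0.00020, rho = 0.820, permutation p = 0.00016). The permutation p of r was 0.00060 after adjustment over 3 such relations. Without the 2 samples farthest from the median, r was 0.732. Within the 9 healthy samples r was 0.902 (exact permutation p = 0.00121) and within the 9 HCV samples 0.684 (exact permutation p = 0.0434, adjusted p = 0.13 over 6 relations in the exact test). Without the 2 farthest samples the HCV value was 0.355, so the relation there rests on those samples. With group means removed, these values show that the genes varied together among people and cannot show why the groups differed. JUN itself had a log2 difference of 0.85 relative to RPLP0 (limma adjusted p = 0.159). A shared response could have arisen in the body or during blood handling, and the labels give no handling times to separate these.

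CCNA1 and MPO are both expressed in early myeloid cells, so such cells in the blood could raise both. Within groups, relative to the median gene, the pair did not rise together (r = 0.034, permutation p = 0.885, rho = 0.10, permutation p = 0.695; r = -0.17 without the 2 farthest samples). This leaves the explanation open, since 18 samples leave r imprecise and CCNA1 was scarce.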
